A study of Mus musculus with 6 samples.

How the data were processed

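RNA from 6 samples of isolated mouse intestinal crypts, 3 control and 3 Arid1a knockout, was labelled with Cy3 and hybridised to Agilent one-colour arrays, 1 per sample, per the labels. The spots' intensity was extracted with Agilent Feature Extraction, version 12.0.3.1 per the file headers and 11.5.1.1 per the submitters' processing notes. Per the file headers, the processed intensity of a spot is already background-subtracted within its array and was not scaled between arrays. The flags for signal well above background, outliers and saturation are the authors' Feature Extraction values, per the file headers. The authors' deposited series table holds log2 values. Set against the scanner files, it was on the same 75th percentile scale and centred on each probe's median over the 6 arrays, with column medians of 0.196, 0.0610 and -0.325 for controls 1 to 3 and -0.0717, 0.216 and -0.184 for knockouts 1 to 3. It served only as an alternative.

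From the scanner files, control spots and outlier-flagged spots were left out and the spots of a probe averaged. The log2 processed signal minus each array's 75th percentile was taken. That percentile was at a signal of 295, 279 and 290 on controls 1 to 3 and 292, 206 and 205 on knockouts 1 to 3, and no spot was saturated. The number of arrays limits the precision. Probes were named through the unversioned accession in the systematic name, matched to a RefSeq gene table of assembly GRCm38.p6, which served for names and for the chromosome a gene lies on. Of 56605 probes, 33767 received a symbol and 22838 did not. Since the array's own coordinates are on another build, per the file headers, no coordinates are given. Probes well above background on at least 3 of the 6 arrays were kept (26746, of which 19392 had a symbol). For each of 13492 genes the probe with the highest mean over all arrays was used, and 4726 genes had several kept probes. Among genes named by the rule given below, Bcl2l11 and Lrp4 had probes of opposite sign. For genes named outside that rule the probes were not compared singly. Of these, Muc2 was negative on its brightest probe and at 0.15 with the mean of its probes. Where a group was not well above background on any array, a bound is given as "at least N-fold": the bright group's mean against, per array, the higher of the lowest signal among probes well above background and the dim probe's own.

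Before the data were examined, the groups, the design, the alternatives, 34 gene lists and the rule for named genes were fixed. Groups followed title and description, which contradict source name and genotype for knockout 2 and control 3. The fit was limma (version 3.58.1, R 4.3.3) with group as the only term, eBayes and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05, two-sided. Lists with at least 5 measured genes (31 tested, a list of sex-linked genes being given per array only) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. Of the 10 lists called at the preset, 0 held with an estimated correlation. The fry test, which asks whether the genes of a list move on balance one way, called 10 lists, of which 6 were also called by camera; the other 4 were regenerating epithelium, colon, fibroblast and endothelial cell. The named genes were Arid1a, Sox9, the 10 largest changes in each direction among called genes whose groups did not overlap, leaving out clone and predicted-gene names, and up to 4 members with the smallest p from each list described. Some genes under this rule and 1 gene family are not reported here. All named genes outside this rule were chosen after their values were seen, among them Osr2, Pnliprp2, Dll4 and the single genes given for symbol families.

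On simulated data with 13492 genes for knockout against control, 200 of them changed, the fit recovered 40% of 50 genes changed 2-fold, 62% at 2.83-fold, 66% at 4-fold and 90% at 8-fold, with 5 false calls. The noise was normal, independent between genes and equal in SD for both groups. Fewer genes were changed than were called in the data, so these rates hold for the simulated setting only. Camera called the 1 shifted list and 0 of 30 unchanged lists, which were simulated without correlation between genes.

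Slide and scan day split the arrays in the same way: controls 1 and 2 and knockouts 1 and 2 on slide 1, control 3 and knockout 3 on slide 2. Alternatives were the labels, the replicate number or the slide as a block, slide 1 alone, the background correction, 2 other normalizations, the filter on dim probes, the choice of probe, the variance model, array weights, the deposited table, the thresholds and each array left out. The normexp correction (offset 50) was run on median spot and background signals because a mean signal column was not analysed here. Sex as a block, the 75th percentile over probes detected on all arrays, the counts of list members without single arrays, and the list of BAF subunits without Arid1a were chosen after seeing the data.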

Results

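Gene expression was measured in isolated intestinal crypts of mice in which both alleles of Arid1a carry flanking recombination sites. Crypts are the pockets of the intestinal lining that hold its stem cells, and Arid1a encodes a DNA-binding subunit of the BAF chromatin-remodelling complex. In the 3 knockout samples Cre recombinase under the Villin promoter, which is active in the intestinal epithelium, deletes Arid1a. The 3 control samples carry the same Arid1a alleles without Cre. Each sample was hybridised to 1 one-colour array. The labels of 2 arrays contradict each other: for knockout 2 the title and description give the knockout, while the source name and genotype give the control, and for control 3 it is the other way round. Groups here follow title and description. Between 41.7% and 54.7% of the 56605 probes were well above background on an array, and 13492 genes were tested. The labels do not say whether the 3 samples of a group came from separate animals, so p-values measure the spread between these samples. Fold changes below are log2 values, knockout minus control, ± SE with n = 3 per group, and adjusted p-values come from limma with Benjamini-Hochberg adjustment.

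Arid1a, the deleted gene, was lower on all 3 knockout arrays. Its log2 signal relative to the array's 75th percentile was 3.71, 3.47 and 4.01 on control arrays 1 to 3, and 2.20, 2.07 and 2.51 on knockout arrays 1 to 3. The log2 fold change of Arid1a was -1.47 ± 0.21, a 2.77-fold fall (adjusted p = 0.00733). Both arrays with contradicting labels lay with the group that title and description give them. A single probe measured Arid1a, and its position relative to the deleted part is not given in the sources used here. The difference was -1.45 on slide 1, which held controls 1 and 2 and knockouts 1 and 2, and -1.5 on slide 2, which held control 3 and knockout 3. With slide as a block the adjusted p was 0.00452. Without both arrays with contradicting labels the log2 fold change was -1.23 (adjusted p = 0.0978).

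Sox9, a transcription factor of stem and Paneth cells that the series title names, had a lower mean in the knockout group, but the difference did not pass the test. Its brighter probe gave 1.72, 1.16 and 0.37 on control arrays 1 to 3, and 0.66, -0.35 and -2.25 on knockout arrays 1 to 3. The log2 fold change of Sox9 was -1.73 ± 0.74 (adjusted p = 0.15). The dimmer probe differed by -0.77 and was lower on every knockout array than on any control array. It gave -1.79, -1.63 and -2.14 on control arrays 1 to 3, and -2.49, -2.83 and -2.56 on knockout arrays 1 to 3. Within slides the difference on the brighter Sox9 probe was -1.28 on slide 1 and -2.62 on slide 2. With slide as a block its adjusted p was 0.0424. Without knockout 1 the log2 fold change was -2.38 (adjusted p = 0.0418), and without knockout 3 it was -0.93 (adjusted p = 0.260).

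**Figure D1:**
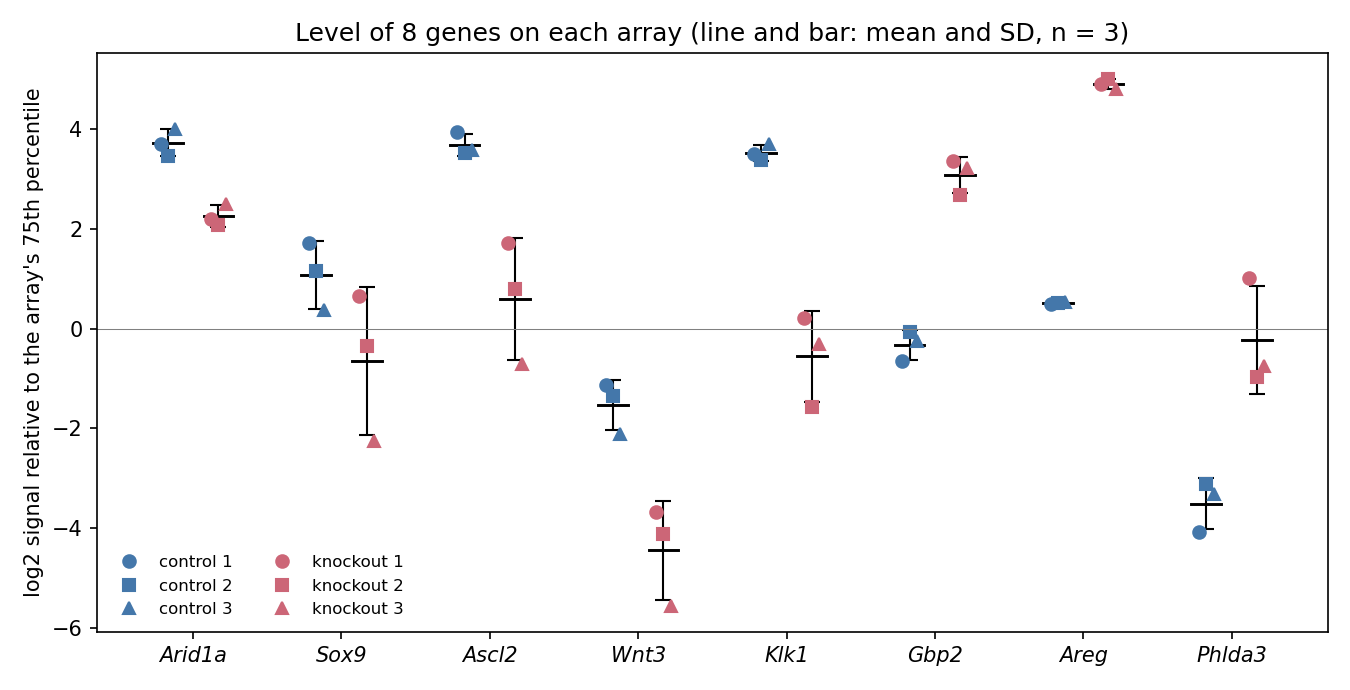
Log2 signal relative to the array's 75th percentile (vertical axis) of 8 genes (horizontal axis) on each of the 6 arrays; points are arrays, horizontal lines the group means and bars the SD, n = 3. Arid1a lies between 2.07 and 2.51 on the knockout arrays and between 3.47 and 4.01 on the control arrays, while the values of the brighter Sox9 probe overlap between the groups.

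The comparison of knockout with control crypts asked how expression differs when Arid1a is deleted in this tissue. It found 2011 genes past an adjusted p of 0.05, of which 982 were higher and 1029 lower in the knockout group. At least a 2-fold difference was seen for 652 of the higher and 697 of the lower genes. For 5355 genes (39.7%) the 3 arrays of one group all lay beyond those of the other, where chance gives 10%. The median SD was 0.20 among control arrays and 0.30 among knockout arrays. With the array median in place of the 75th percentile, the share of called genes that were higher was 28.8% instead of 48.8%, and the median gene shifted by -0.26. On slide 1 alone 689 genes passed, and 97.8% of these had the same sign on slide 2, which held 1 array per group. Leaving out control 1, 2 or 3 gave 638, 789 and 825 genes, and leaving out knockout 1, 2 or 3 gave 4033, 928 and 1452. With sex as a block, which was uneven between the groups, 1339 genes passed, 1244 of them among the 2011 in the same direction. Without both arrays with contradicting labels 320 genes passed, 293 of them among the 2011 in the same direction. Grouped by source name and genotype instead, 0 genes passed in limma, with 207 at an unadjusted p under 0.05.

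Many of the genes with the largest increases were near or below background in control crypts. Anxa10, a calcium-dependent phospholipid-binding annexin, rose by 9.96 ± 0.58 (adjusted p = 0.000506) and was well above background on 1 of the 3 control arrays. Penk, the precursor of the enkephalin peptides, rose by 3.50 on its dimmer probe. Its brighter probe was not well above background on any control array and was at least 101.7-fold higher in the knockout (adjusted p = 0.000367). By the same kind of bound Rtl5 was at least 13.9-fold higher, Eomes, a T-box factor of cytotoxic lymphocytes, at least 11-fold, Adam2 at least 9.60-fold, Ifng, which encodes interferon gamma, at least 8.68-fold, and Fibin at least 8.01-fold. Serping1, the inhibitor of the complement protease C1, was well above background on all 3 control arrays and rose by 6.27 ± 0.29. The interferon-inducible GTPases Gbp8 and Gbp4 rose by 5.50 ± 0.64 and 5.28 ± 0.30, with 2 of 3 control arrays well above background for each.

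Genes of several kinds were among the largest decreases. Lct, which encodes lactase, had a log2 fold change of -5.10 ± 1.01 (adjusted p = 0.0220), with knockout values of 2.26, 1.38 and 5.64 against a control mean of 8.19. Cubn, the receptor for intrinsic factor and vitamin B12, changed by -5.70 ± 1.20, and Car4, a membrane-bound carbonic anhydrase, by -6.37 ± 0.99, each with 2 of 3 knockout arrays well above background. For Gsdmc3 and Gsdmc4, close relatives in the gasdermin family, the changes were -6.59 ± 0.50 and -5.98 ± 0.56, each with 1 of 3 knockout arrays well above background. The extracellular matrix gene Vwa1 was at least 73.9-fold lower, the carboxylesterases Ces1d and Ces1g at least 26.3-fold and 16.7-fold, the circadian-output factor Hlf at least 9.97-fold and Zfp462 at least 7.68-fold. These 5 genes were not well above background on any knockout array. Near-identical paralogs of the Gsdmc, Ces1 and Gbp genes share sequence, so their probes may not tell single members apart.

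Interferon-responsive genes rose together. Of 28 measured members, 18 rose and 0 fell, and 25 passed when adjusted over the list alone. Gbp2, an interferon-inducible GTPase, rose by 3.41 ± 0.25, Igtp, another such GTPase, by 2.84 ± 0.22, Usp18, which removes the ubiquitin-like protein Isg15 from its targets, by 2.64 ± 0.24, and Isg15 itself by 2.07 ± 0.16. All 28 members had a positive log2 fold change, with a median of 1.17, and none was lower at an unadjusted p under 0.05 (0 genes). The list passed camera with its preset correlation (adjusted p = 3.52e-14) but not with an estimated one (adjusted p = 0.363 with an estimated correlation), and fry gave an adjusted p of 0.00277. The number that rose was 12, 13 and 14 without control 1, 2 or 3, 20, 13 and 15 without knockout 1, 2 or 3, and 6 without both arrays with contradicting labels. The list's median was 1.07 on slide 1 and 1.26 on slide 2, with an adjusted p of 8.73e-13 with slide as a block. Markers of immune cells had a smaller shift. In the list of T cells and intraepithelial lymphocytes 1 of 19 members rose, Thy1 by 1.92 ± 0.37, and the median was 0.31. The samples varied widely, with this list's mean deviation from the controls at -0.86, 0.46 and 0.40 on controls 1 to 3. On knockouts 1 to 3 it was 0.74, -0.38 and 0.88, while the interferon list lay at 1.35, 1.21 and 1.51.

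Some members of the crypt base stem cell list fell in the knockout. Of 27 measured members, 7 fell and 0 rose, with 13 and 0 when adjusted over the list alone, and 2 were higher at an unadjusted p under 0.05. Ascl2, a transcription factor of the intestinal stem cell, had a log2 fold change of -3.09 ± 0.57 (adjusted p = 0.0181). For Prom1, a membrane protein of crypt base cells, the change was -2.05 ± 0.32, for Rgmb -0.99 ± 0.19, with 1 of 3 knockout arrays well above background and -0.38 on its other probe, and for Axin2, a feedback inhibitor of Wnt signalling, -0.85 ± 0.16. Lgr5, the R-spondin receptor that marks these stem cells, was singled out after its values were seen. It had a log2 fold change of -2.24 ± 0.82 and did not pass (adjusted p = 0.110). The list's median was -0.99, -0.81 on slide 1 and -1.43 on slide 2, and its camera adjusted p was 0.000775 with the preset correlation, 0.000525 with slide as a block and 0.636 with an estimated correlation, while fry did not call it (adjusted p = 0.0934). Leaving out control 1, 2 or 3, 1, 2 and 1 members fell, without knockout 1, 2 or 3 it was 14, 3 and 8, and without both arrays with contradicting labels 0, with 9 at an unadjusted p under 0.05.

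Some members also fell in the list of Wnt signalling targets, which shares genes with the stem cell list. Of 22 measured targets, 7 fell and 0 rose, with 13 and 2 when adjusted over the list alone, and 2 were higher at an unadjusted p under 0.05. Nkd1, an antagonist of the pathway, was at least 2.33-fold lower (adjusted p = 0.00167), being not well above background on any knockout array. Sox4 changed by -1.78 ± 0.34, and Lrp4 by -1.73 ± 0.25 on its brightest probe, although its other probes ranged from -1.53 to 0.05. The median over targets was -1.06, with -0.93 on slide 1 and -1.38 on slide 2. Camera gave an adjusted p of 0.000353 with the preset correlation, 0.000274 with slide as a block and 0.557 with an estimated correlation, and fry 0.0243. The number that fell was 2, 2 and 2 without control 1, 2 or 3, 13, 4 and 7 without knockout 1, 2 or 3, and 1 without both arrays with contradicting labels.

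Genes of the Paneth cell, the antimicrobial secretory cell of the crypt base, had the lowest median of the 31 lists tested. Of 19 measured members, 8 fell and 1 rose, and 11 fell when adjusted over the list alone. With sex as a block 3 members fell. Habp2 changed by -4.32 ± 0.95 and Clps, a pancreatic colipase, by -2.51 ± 0.44. The exocrine pancreas list also had a negative median, -1.55, with 11 of 13 genes negative, but did not pass (camera adjusted p = 0.0853). Wnt3, a niche signal of Paneth cells, was at least 5.21-fold lower (adjusted p = 0.0155). Cd24a, also a tuft cell gene, changed by -1.51 ± 0.29. The member that rose was Pnliprp2, a lipase, by 2.02 on the log2 scale. Lyz1, the Paneth lysozyme, singled out after its values were seen, had a log2 fold change of -1.53 ± 0.59 and did not pass (adjusted p = 0.125). The median was -2.42, with -1.48 on slide 1 and -3.36 on slide 2, and camera gave an adjusted p of 0.000202 with the preset correlation, 5.13e-06 with slide as a block and 0.636 with an estimated correlation, while fry did not call the list (adjusted p = 0.102). Leaving out control 1, 2 or 3 left 0, 0 and 3 members that fell, each with 9 at an unadjusted p under 0.05. Without knockout 1, 2 or 3 the number was 12, 2 and 13, and without both arrays with contradicting labels it was 0, with 10 at an unadjusted p under 0.05.

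Some goblet cell genes, of the mucus-secreting lineage, also fell. Of 24 measured members, 11 fell and 0 rose, with 16 and 1 when adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05. With sex as a block 6 members fell. Klk1, a kallikrein protease, changed by -4.09 ± 0.44, Guca2a, the hormone guanylin, by -2.84 ± 0.44, Creb3l4, a secretory-pathway factor, by -1.5 ± 0.20 and Rep15 by -1.06 ± 0.17. Muc2, the main secreted mucin, did not pass, at -0.06 ± 0.34 (adjusted p = 0.914, chosen after its values were seen). Goblet members had a median of -0.83, with -0.77 on slide 1 and -0.66 on slide 2. Camera's adjusted p was 1.87e-05 with the preset correlation, 1.82e-05 with slide as a block and 0.557 with an estimated correlation, and that of fry 0.00890. Without control 1, 2 or 3 the count was 3, 5 and 4, without knockout 1, 2 or 3 it was 13, 5 and 9, and without both arrays with contradicting labels it was 1.

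Tuft cell genes, of the chemosensory lineage, included 4 of 18 measured members that fell and 0 that rose, with 9 and 0 when adjusted over the list alone and 0 higher at an unadjusted p under 0.05. Alox5ap and Alox5, of leukotriene synthesis, changed by -1.79 ± 0.28 and -1.62 ± 0.32, and Plcg2 by -0.84 ± 0.16. The median was -0.86, with -1.18 on slide 1 and -0.11 on slide 2, and the camera adjusted p was 0.000911 with the preset correlation, 0.00216 with slide as a block and 0.636 with an estimated correlation, while fry did not call the list (adjusted p = 0.102). Without control 1, 2 or 3 the count was 1, 1 and 2, without knockout 1, 2 or 3 it was 4, 1 and 7, and without both arrays with contradicting labels it was 0, with 6 at an unadjusted p under 0.05. Enteroendocrine genes did not pass as a list (camera adjusted p = 0.111), but among 26 measured members 3 rose and 1 fell, with 3 and 4 when adjusted over the list alone, and 20 had a negative log2 fold change. Pcsk1, a prohormone convertase, rose by 2.66 ± 0.21, the regulator Pax4 by 2.0 ± 0.51 and Sct, secretin, by 0.996 ± 0.22, whereas Nts, neurotensin, changed by -3.67 ± 0.52, with 2 of 3 knockout arrays well above background.

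**Figure D2:**
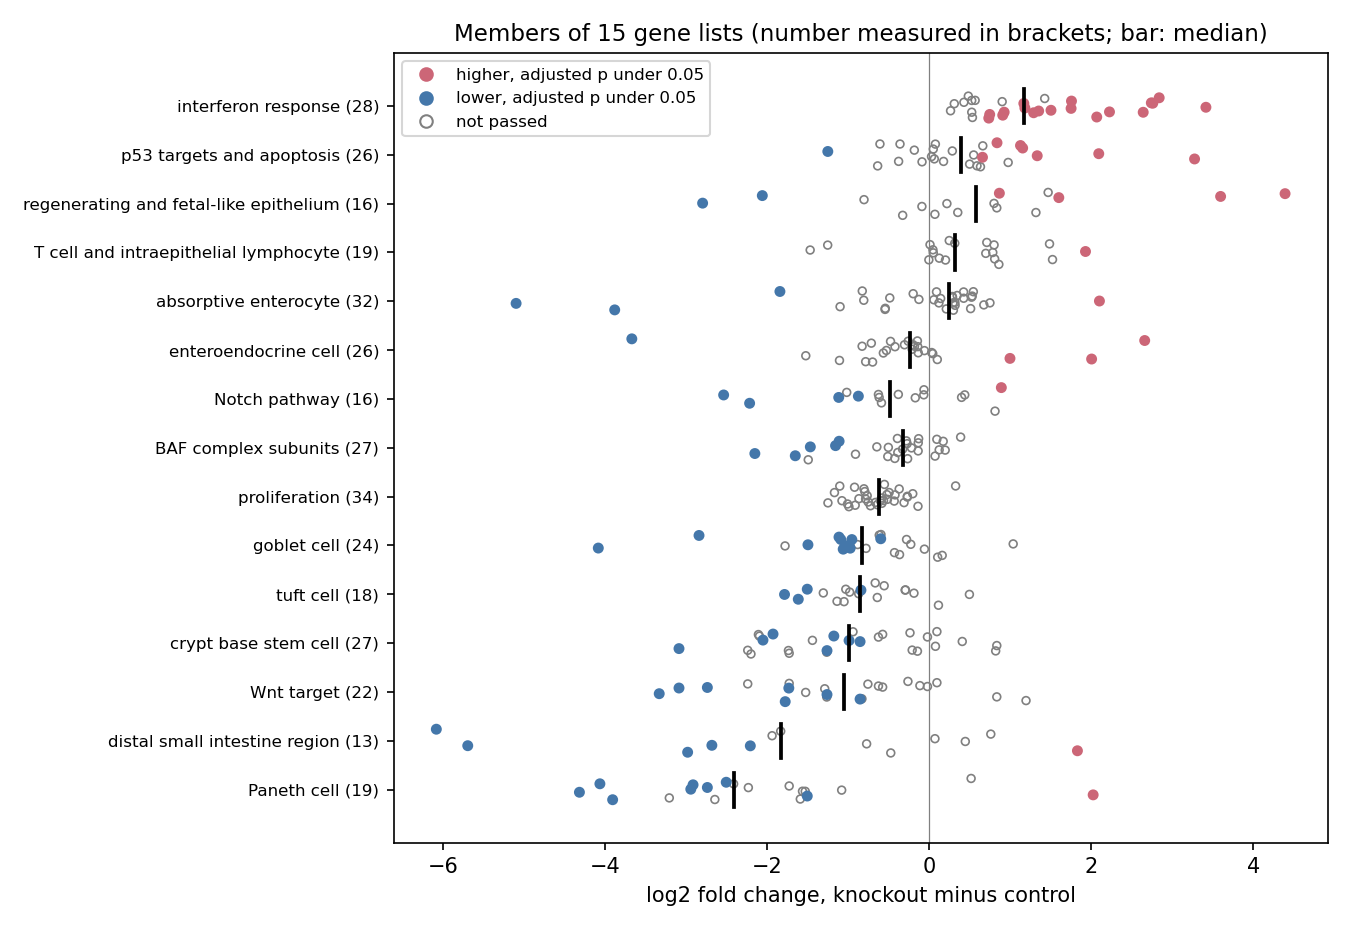
Log2 fold change, knockout minus control (horizontal axis), of each measured member of 15 gene lists (vertical axis, number of measured members in brackets); filled points passed an adjusted p of 0.05, open points did not, and black bars are medians. The interferon response list has the highest median, 1.17, and the Paneth cell list the lowest, -2.42.

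Proliferation genes were lower on average, with no single member past the test. Of 34 measured members, 0 passed in limma, 11 were lower at an unadjusted p under 0.05 and 33 had a negative log2 fold change. Mcm6 and Mcm2, subunits of the replicative helicase, had log2 fold changes of -1.25 ± 0.37 (adjusted p = 0.0637) and -1.17 ± 0.43, Cenpf -0.80 ± 0.28 and Pcna, the sliding clamp, -0.57 ± 0.21. Mki67, chosen after its values were seen, had -0.75 ± 0.30. The median was -0.62, with -0.45 on slide 1 and -1.04 on slide 2. The camera adjusted p was 0.000338 with the preset correlation, 0.000525 with slide as a block and 0.652 with an estimated correlation, and fry did not call the list (adjusted p = 0.272). The list's mean deviation from the controls was 0.08 on knockout 1, -0.89 on knockout 2 and -1.12 on knockout 3. Over the same arrays the crypt base stem cell list lay at -0.44, -0.89 and -1.64, and the absorptive enterocyte list moved the opposite way, at -0.67, -0.20 and 0.28, against -0.14, -0.13 and 0.27 on control arrays 1 to 3. With array quality weights 31 members passed as lower, a setting in which 3608 of all genes did. Without knockout 1, 26 members fell, where 2323 of all genes did. With any other single array left out, or both arrays with contradicting labels, 0 members fell, with 0 to 5 at an unadjusted p under 0.05.

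Targets of p53 and genes of apoptosis went mostly the other way. Of 26 measured members, 7 rose and 1 fell, with 12 and 1 when adjusted over the list alone. With sex as a block 4 members rose. Phlda3, an inhibitor of the kinase Akt and a p53 target, rose by 3.27 ± 0.55, with 2 of 3 control arrays well above background, and the death receptor Fas by 1.13 ± 0.21. Bcl2l11, a pro-apoptotic member of the Bcl2 family, had -1.25 ± 0.21 on its brightest probe, while its other probes ranged from -0.65 to 0.09. The median was 0.39, with 0.39 on slide 1 and 0.20 on slide 2, and the camera adjusted p was 0.0283 with the preset correlation, 0.0242 with slide as a block and 0.557 with an estimated correlation (fry adjusted p = 0.0189). Without control 1, 2 or 3 the number that rose was 0, 1 and 2, without knockout 1, 2 or 3 it was 10, 3 and 3, and without both arrays with contradicting labels it was 0, where at least 9 had an unadjusted p under 0.05.

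The list of regenerating and fetal-like epithelium was called by fry (adjusted p = 0.00562, higher) but not by camera (adjusted p = 0.0749), and it held a pair of strong increases. Areg and Ereg, ligands of the epidermal growth factor receptor, rose by 4.39 ± 0.14 (adjusted p = 0.000209) and 3.60 ± 0.23, Ereg with 1 of 3 control arrays well above background. Of 16 measured members 4 rose and 2 fell, the latter being Krt7, a keratin, at -2.80 ± 0.30 and Ly6e at -2.06 ± 0.36. Without single arrays the number that rose was 2, 3 and 3 for control 1, 2 and 3 and 6, 3 and 2 for knockout 1, 2 and 3. In the Notch list 4 of 16 members fell, among them Lfng, a glycosyltransferase that modifies Notch receptors, which was at least 2.61-fold lower, Nrarp at -2.22 ± 0.36 with 2 of 3 knockout arrays well above background, Notch2 at -1.12 ± 0.18 and Rfng at -0.88 ± 0.19. The Notch ligand Dll4 rose by 0.89 on the log2 scale, and the list as a whole did not pass (camera adjusted p = 0.111). With control 1, 2 or 3 left out 0, 3 and 2 Notch members fell, with knockout 1, 2 or 3 left out 6, 3 and 3, and with both arrays with contradicting labels left out 0, where at least 4 had an unadjusted p under 0.05.

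Among subunits of the BAF complex other than Arid1a, the ATPase Smarca2 changed by -2.15 ± 0.27 (adjusted p = 0.00532), Bcl11b by -1.65 ± 0.32 and Bcl7a by -1.11 ± 0.28. Without Arid1a 4 of 26 measured subunits fell and 0 rose, with a median of -0.31 and a camera adjusted p of 0.0164 with the preset correlation and 0.618 with an estimated correlation. With Arid1a counted, as the list was fixed, 5 of 27 fell and 0 rose, and 1 was higher at an unadjusted p under 0.05. The list's median with Arid1a was -0.33, with -0.29 on slide 1 and -0.38 on slide 2, and the camera adjusted p was 0.00681 with the preset correlation, 0.00852 with slide as a block and 0.557 with an estimated correlation (fry adjusted p = 0.0234). Without control 1, 2 or 3 the number that fell was 2 each time, without knockout 1, 2 or 3 it was 8, 2 and 4, and without both arrays with contradicting labels it was 0, with 5 at an unadjusted p under 0.05.

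Some markers of distal small intestine fell. Of 13 measured members, 5 fell and 1 rose. Besides Ces1g and Cubn these were Osr2, by -2.98 on the log2 scale, Amn, the partner of Cubn in vitamin B12 uptake, at -2.21 ± 0.26, and Fabp6, the ileal bile acid-binding protein, which was at least 3.29-fold lower. Slc51b, a subunit of the basolateral bile acid exporter, rose by 1.83 ± 0.35. The median was -1.83, with -2.24 on slide 1 and -0.78 on slide 2, and the camera adjusted p was 0.0354 with the preset correlation, 0.0350 with slide as a block and 0.557 with an estimated correlation (fry adjusted p = 0.00890). The number that fell was 3, 3 and 3 without control 1, 2 or 3, 5, 4 and 7 without knockout 1, 2 or 3, and 1 without both arrays with contradicting labels. Markers of the colon included 4 of 10 that fell, with Car4 among them, and 1 that rose (camera adjusted p = 0.111, fry 0.0346). Of 13 proximal markers 3 fell, with Ppp1r1b at -1.52 ± 0.20 and Lct among them, and 0 rose, with 0 higher at an unadjusted p under 0.05. The proximal list's median, 0.28, was positive while its mean, -0.57, and its camera direction were negative (adjusted p = 0.766).

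Absorptive enterocyte genes did not pass as a list (camera adjusted p = 0.729). Of 32 measured members 3 fell and 1 rose: besides Lct, the peptidases Xpnpep2 and Enpep changed by -3.88 ± 0.36 and -1.84 ± 0.46, and the fructose transporter Slc2a5 rose by 2.10 ± 0.29. Their median, 0.25, was positive and their mean, -0.20, negative. In the antimicrobial and acute inflammation list 3 of 21 members rose and 2 fell (camera adjusted p = 0.174). The chemokines Ccl20 and Cxcl10 rose by 3.08 ± 0.48 and 2.03 ± 0.18, and Reg3a and Lcn2 had -2.84 ± 0.36 and -1.83 ± 0.33.

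Markers of cells outside the epithelium moved unevenly. Of 6 measured fibroblast genes 2 rose, Serping1 and Thy1, which is also in the T cell list (camera adjusted p = 0.0980, fry 0.0189). Of 6 endothelial genes Lyve1, a lymphatic vessel receptor, rose by 4.64 ± 0.42, while Esam was at least 2.62-fold lower (camera adjusted p = 0.355, fry 0.00890). Of 13 myeloid genes 3 rose and 2 fell (camera adjusted p = 0.429). Mrc1 rose by 1.28 ± 0.19 with 1 of 3 control arrays well above background, and Cd68 by 0.87 ± 0.16, whereas Lyz2, the macrophage lysozyme, changed by -3.43 ± 0.76. Whether the Lyz2 probe also reads Lyz1, the Paneth lysozyme, was not tested. In 6 smooth muscle genes 1 rose, in 5 mast cell genes 1 fell, in 7 neuron and glia genes 1 rose and 1 fell, and in 13 exocrine pancreas genes 2 fell, with camera adjusted p of 0.121, 0.926, 0.766 and 0.0853. Of 4 B and plasma cell genes and 2 red blood cell genes 0 passed in limma, with 2 and 0 at an unadjusted p under 0.05, and these lists were too short for camera. The remaining lists gave no call as a whole in camera: 4 of 21 handling stress genes rose (adjusted p = 0.0529), 2 of 23 endoplasmic reticulum stress genes rose (0.111), 2 of 23 matrix and adhesion receptor genes rose (0.0552; 0.0417 with slide as a block), 1 of 8 plus-four stem cell genes rose and 1 fell (0.697), 1 of 23 bile acid and cholesterol genes rose and 2 fell (0.832), and 0 of 8 MHC class II genes changed (0.871), with 0 at an unadjusted p under 0.05. With slide as a block the smooth muscle list passed (adjusted p = 0.0450). Without the block, neither this list nor that of matrix and adhesion receptors passed in other tests. Each had an adjusted p of 0.636 in camera with an estimated correlation and 0.220 with fry.

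**Figure D3:**
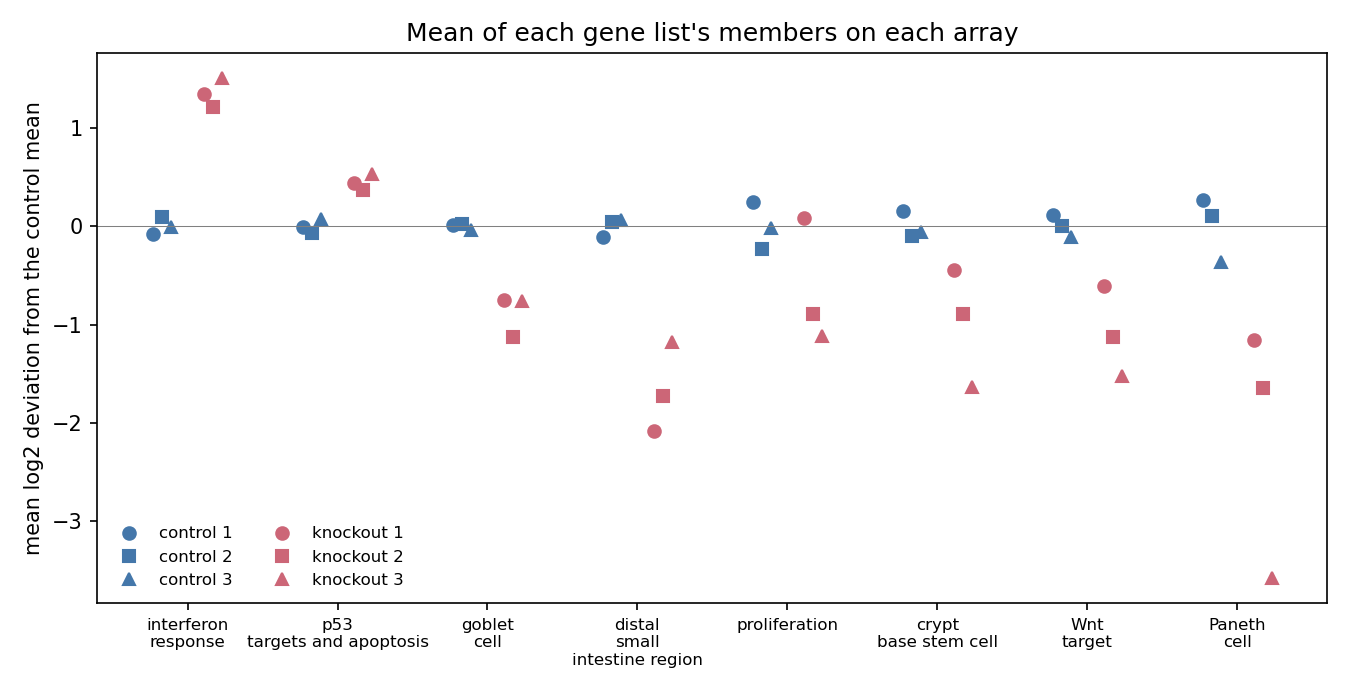
Mean log2 deviation of the members of 8 gene lists from their control means (vertical axis) on each of the 6 arrays (points), by list (horizontal axis). The interferon list lies at 1.35, 1.21 and 1.51 on knockout arrays 1 to 3, while the proliferation list lies at 0.08, -0.89 and -1.12.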

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

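The explanations tested in this part, and the counts of splits, were chosen after the results were seen, while quantile normalization was a setting chosen before. Probes that the gene table gave no symbol lie outside the gene-level comparison. Of 7353 such probes above the same filter, 184 were higher and 67 lower in the knockout group in limma at an adjusted p of 0.05.

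The proliferation list differed between the knockout arrays: its mean deviation from the controls was 0.08 on knockout 1, -0.89 on knockout 2 and -1.12 on knockout 3, against an SD of 0.24 between controls. Knockouts 1 and 2 were on the same slide and lay 0.97 apart, against an SD of 0.34 for a difference between 2 arrays, so slide does not account for the gap between them; knockout 3 was the only knockout array on slide 2, and slide stays open for it. After quantile normalization the range over the knockout arrays was 1.23, with a control SD of 0.20. On the 75th percentile scale it was 1.20. Both settings put the arrays on a common scale, so scale alone does not account for the spread. Other effects of unequal signal stay open. The 75th percentile signal was 292, 206 and 205 on knockouts 1 to 3, against 279 to 295 on the controls. Incomplete loss of the Arid1a transcript on knockout 1 stays open: Arid1a there was 0.13 above knockout 2 and differed from knockout 3, the highest knockout array, by -0.31, both within the SD of 0.38 for a difference between 2 arrays, and the position of its probe relative to the deleted part is not given in the sources used here. A larger share of differentiated cells on knockouts 2 and 3 stays open too. The lower of these arrays in the absorptive enterocyte list lay 0.47 above knockout 1, more than the SD of 0.33 for such a difference, but at -0.20 it was not above the control arrays. Time since deletion, age and litter were not tested.

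Interferon response genes rose in the knockout group, with a median of 1.17. If immune cells among the knockout crypts brought these transcripts with them, immune markers should rise too. The 36 measured markers of T, B and myeloid cells had a median of 0.31 (95% bootstrap interval 0.10 to 0.74). The interval was 0.74 to 1.63 for the interferon list, and 0 of the markers are in that list. The interferon median was higher by 0.87, with a 95% bootstrap interval from 0.18 to 1.33. These intervals resample genes, so they do not measure the spread between samples. That spread was wide for the T cell list, whose mean deviation ran from -0.86 to 0.46 on controls and from -0.38 to 0.88 on knockouts. Interferon secreted by few immune cells would not need such a rise of the markers, so immune cells stay open as a cause. The sex of the animals, read from Y-linked genes, was uneven, and of the 18 interferon genes past the threshold 13 stayed past it with sex as a block, which argues against sex as the whole cause. Slide was balanced over the groups, and the list's median was 1.07 on slide 1 and 1.26 on slide 2. A response of the knockout epithelium itself was not tested. A small number of activated lymphocytes that secrete interferon gamma, whose gene Ifng rose, stays open, as does strain background, which the labels give as mixed.

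Of 13 distal small intestine genes 5 were lower and 1 higher past the threshold, with a median of -1.83, and 4 of the 13 had a positive log2 fold change; the list did not pass camera with an estimated correlation (adjusted p = 0.557). If the knockout crypts came from a more proximal segment, proximal genes should be higher. The 13 proximal genes had a median of 0.28 with a 95% bootstrap interval, resampling genes, from -0.71 to 0.42. Of them 8 had a positive log2 fold change, but past the threshold 3 fell and 0 rose, and their mean was -0.57. With values going both ways, the segment and the genotype cannot be told apart for these genes. The labels do not name the segment of intestine, which keeps this open, and a change of regional identity within the same segment was not tested.

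Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 2011 genes and the highest of the others 3, and 1 of the 10 splits gave as many genes. For the gene lists, camera at its preset correlation called 10 in the real split and up to 15 in another, the one that follows source name and genotype, and 5 of the 10 splits gave as many lists. Called lists at the preset correlation therefore do not set the real split apart from the others. The proliferation list, called at the preset correlation, had 0 members past limma with all arrays weighted alike and the settings fixed for the comparison (11 lower at an unadjusted p under 0.05). With array quality weights 31 were lower, where 3608 of all genes were, and without knockout 1 26 were, where 2323 of all genes were. The number was 5 with the replicate block and 1 each with trend and robust eBayes, median scaling and the mean of a gene's probes.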

How the results depend on the processing

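Sex as a block and the 75th percentile over probes detected on all arrays were chosen after seeing the data, all other settings before. The cause of a change was not tested unless given here. Arid1a kept its direction and side of the threshold in 22 of 24 settings and Sox9 in 20 of 24, with adjusted p from 0.000515 to 0.9992 and from 0.0174 to 0.9992. With groups by source name and genotype, 0 genes were higher and 0 lower, with 123 and 84 at an unadjusted p under 0.05, and Arid1a was at -0.18. Without both arrays with conflicting labels, which leaves 2 against 2, 177 genes were higher and 143 lower, Arid1a was at -1.23 (adjusted p = 0.0978) and 17 lists passed. Slide 1 alone, also 2 against 2, gave 319 higher and 370 lower. Median scaling gave 561 higher, with the median gene at -0.26, no filter on dim probes 366 higher and 331 lower among more genes, at least 2-fold 652 higher, an adjusted p under 0.10 1644 higher and 1801 lower, array quality weights 3489 higher and 3608 lower with Sox9 at -1.64 (adjusted p = 0.0174), and sex as a block 643 lower, with 3 Paneth and 6 goblet members lower and 4 p53 members higher in place of 8, 11 and 7, and 10 named genes without their call. Camera with an estimated correlation called 0 lists, and fry 10.

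The labels do not state whether the replicate numbers pair the samples, and the check does not settle it. Deviations from group means correlated at 0.246, 0.0797 and 0.352 for numbers 1 to 3, and every array correlated best with its own number. Pairs of unlike number lay between -0.281 and 0.0205. Control 3 and knockout 3 also shared slide 2, so slide and pairing cannot be told apart for number 3. By Y-linked genes control 1 and knockout 1 were both male, and control 2 and knockout 2 both female. Shared sex within slide 1 and pairing therefore cannot be told apart for numbers 1 and 2. Pairs of 1 sex but unlike number lay on different slides, at -0.281 (control 1 and knockout 3) and -0.0981 (control 3 and knockout 2). With the replicate block 2733 genes passed, 1883 of them shared with the 2011 in the same direction, Sox9 stayed at -1.73 with an adjusted p of 0.0300 and 10 lists passed. With slide as a block 2502 genes passed, 1934 shared, and Sox9, at -1.73, had an adjusted p of 0.0424.

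With each array left out in turn, the number of genes higher ranged from 352 (without control 1) to 1710 (without knockout 1) and lower from 286 to 2323, Arid1a from -1.60 to -1.33, Sox9 from -2.38 (without knockout 1, adjusted p = 0.0418) to -0.93 (without knockout 3), and the lists from 9 to 16 (without knockout 2). Of 101 other named genes, 38, 30 and 26 lost their call without control 1, 2 or 3, 1, 21 and 6 without knockout 1, 2 or 3, 57 without both arrays with conflicting labels and 91 with groups by source name and genotype, where 2 more reversed.

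Some signs reversed. With groups by source name and genotype Ccl20 was at -0.016 and Osr2 at 0.25, and list medians were 0.049 (enteroendocrine), -0.065 (antimicrobial), 0.30 (MHC class II), 0.34 (bile acid), -0.17 (proximal), -0.47 (mast cell), -0.037 (neuron and glia) and 0.19 (exocrine pancreas). Without both arrays with conflicting labels MHC class II was at 0.078, bile acid at 0.22 and mast cell at -0.29, and on slide 1 alone bile acid was at 0.053 and mast cell at -0.28. Median scaling put absorptive enterocyte at -0.00175, endoplasmic reticulum stress at -0.093 and mast cell at -0.032. The bile acid list was at 0.12 with no filter on dim probes, 0.25 with probes well above background on all arrays, where the colon list was at 0.17, and 0.093 with sex as a block. The T cell list was at -0.19 with array quality weights, and Muc2 at 0.15 with the mean of its probes. With each array left out, Muc2 ranged from -0.35 to 0.19 (positive without control 1 and knockout 1), MHC class II from -0.31 to 0.049 (positive without knockout 2), bile acid from -0.10 to 0.21 (positive without control 3, knockout 1 and knockout 2) and mast cell from -0.22 (without control 3) to 0.46. Signal over background limits the genes given only as bounds.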

Other observations

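Families of genes that share the start of their symbol were tested for an excess of called genes with Fisher's exact test, one-sided. This test was chosen after single members such as the Gbp genes had been seen, and the chromosome test before its result was seen. Of 446 pairs of family and direction with at least 8 measured genes, 9 passed an adjusted p of 0.05, 8 of them described here, in line with families of related genes moving together, although probes of near-identical paralogs may count 1 change several times. Lower in excess were 18 of 58 cytochrome P450 genes (Cyp) against 4.47 by chance (adjusted p = 8.14e-05), with Cyp2j6 at -2.18 ± 0.28 and Cyp2d10 at -2.41 ± 0.42, and 8 of 13 carboxylesterase genes (Ces), with Ces3a at -3.40 ± 0.46, well above background on 1 of 3 knockout arrays, and Ces2a at -2.02 ± 0.31. Another 3 Cyp genes were higher, Cyp4b1 at 1.88 ± 0.43 among them. Of 12 kallikrein genes (Klk), 8 were lower, all of them Klk1 and its Klk1b paralogs, such as Klk1b8 at -3.91 ± 0.35.

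Higher in excess were 7 of 10 Gbp genes, such as Gbp7 at 3.42 ± 0.22, 5 of 11 Parp genes, such as Parp14 at 1.35 ± 0.25, 12 of 49 Trim genes, such as Trim15 at 2.45 ± 0.29 and Trim30a at 1.54 ± 0.19, while 6 were lower, among them Trim38 at -4.85 ± 0.46 with 1 of 3 knockout arrays well above background, 7 of 18 Ly genes, such as Ly6d at 3.1 ± 0.41, with 1 lower, and 5 of 10 Anxa genes, such as Anxa13 at 1.71 ± 0.29. The median of each of these families kept its sign under quantile, median and normexp settings, except the Trim family, whose median of 0.05 became -0.07 with quantile normalization and -0.20 with median scaling, where the median of all genes was -0.26.

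No chromosome held an excess of called genes past the test. Of 40 pairs of chromosome and direction, 0 passed an adjusted p of 0.05 in Fisher's exact test. At an unadjusted p under 0.05, 4 pairs did.

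From Y-linked genes, control 1 and knockouts 1 and 3 were male, and controls 2 and 3 and knockout 2 were female. Over all tested genes, pairs of control arrays correlated at 0.985 to 0.986 and pairs of knockout arrays at 0.966 to 0.978. Pairs of a control and a knockout array were at 0.923 to 0.954. Control 3 was at 0.985 with both other controls and at 0.940 to 0.951 with the knockouts. Knockout 2 was at 0.973 and 0.978 with the other knockouts and at 0.932 to 0.941 with the controls. This argues against the source name and genotype labels of these arrays. The correlations are across genes, which are not independent replicates.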
